A study of Dictyostelium discoideum with 8 samples.

How the data were processed

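Messenger RNA of AX2 and of chdA-null, chdB-null and chdC-null cells was sequenced in growth (0 h) and after 5 h of cAMP pulses, 8 samples in all, each standing for 2 replicates per the labels. RNA was taken with TRIzol, enriched for mRNA and made into Illumina TruSeq libraries, per the labels. The authors list CASAVA 1.7, TopHat 1.3.0, Bowtie 0.12.7, HTSeq and DESeq for their processing, and the genome build is not given in the sources used here. The deposited values are a signal that the file headers call FPKM, but each column behaves as the mean of the read counts of 2 libraries, each divided by its own library factor. Low values are sums of whole multiples of 2 steps per column.

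The 2 steps of each column were found, and each value was split into the 2 whole counts that give it, where only 1 pair was left. Where several pairs gave a value of at least 1000, those with libraries more than 2 log2 apart were first set aside, which favours a small SD. Values left with more than 1 pair, mostly those of the most abundant genes, entered as 1 value per group, carry no SD and were tested with the spread of the other groups. Which library is 1 or 2 is arbitrary. The splitting was tested on simulated data: of 108472 simulated values 105300.0 were split, 0 of them wrongly. The simulated spread was taken from these same splits, so the limit on the distance between libraries was not tested independently. All gene identifiers were matched to the reference, and 3997 genes had a symbol of their own.

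As fixed before the data were examined, samples were compared with 1 value per group as log2 of the ratio of values plus 5, over genes with a highest value of at least 50 in the pair, and genes at least 2-fold apart were counted without a test. There were 6 mutant against AX2 comparisons, 4 of 5 h against 0 h and 3 differences of differences. limma (3.58.1, trend) tested additive effects of stage and strain over the 8 samples, with 3 residual degrees of freedom. Comparisons of per-replicate counts, a replicate block and a count-model test of the additive design, which had been foreseen for files with separate columns, were not run, because the columns hold merged values that are not whole numbers. Chosen after seeing the data, limma with a trend also compared the 8 groups over the 16 split libraries, on log2 of the value plus 5, for 9982 genes, with a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Words such as rose or fell, the SE and the adjusted p rest on this fit unless the additive model is named.

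The lists were cAMP relay, aggregation adhesion, starvation and density sensing, lysosome and endocytosis, ribosomal proteins, proteasome, DNA replication, cell division, histones, prespore markers, prestalk markers, chromatin regulators, transcription factors, actin genes, actin cytoskeleton and chemotaxis, tiger genes, autophagy, heat shock proteins and polyketide synthases. Lists of transposable elements and the mitochondrial genome had been fixed too but matched 0 genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists and contrasts, and with fry, and their medians were placed among 10000 random lists matched in 20 bins of expression. In the estimate of correlation and in fry on the split libraries an undivided value fills both libraries. The correlation was therefore estimated again over members divided in all groups, after seeing the data, and fry is given for the additive model alone. Named genes are the disrupted genes, the 8 largest rises and 8 largest falls with a symbol of their own per contrast, and members of the lists, up to 4 per list and contrast, by size of change. Near-identical copies, such as the actin, tiger, ponC and small heat shock genes, share reads, which leaves the value of each copy uncertain. The log2 change of a gene near 0 depends on the value added.

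The split-library test was checked on simulated data with the spread of the real libraries: it found 62% of genes raised or lowered 2-fold and 100% of those raised or lowered 4-fold, and called 6 of 8436 unchanged genes. The additive strain test found 78% and 99%, with 10 of 8436 unchanged genes called, and the additive stage test 96% and 100%, with 6. The simulated strains all responded alike to the stage. Differences in response, which the residual of the real additive fit also holds, were left out, so these additive shares do not carry over to it. The 2-fold count without a test found 52% and 100%, with 47 of 8273 unchanged genes counted.

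Alternatives were values added of 1 and 20, no minimum and a minimum of 200, 3-fold, TMM scaling (own code), equal totals, leaving out strains or libraries in turn, shortened lists, removal of a trend with gene length, and leaving out 3 libraries that stood apart. On the split libraries, all of these were chosen after seeing the data, as was the length trend for the 2-fold counts. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.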

Results

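Messenger RNA was sequenced from Dictyostelium discoideum, a social amoeba that grows as single cells and aggregates by relaying pulses of extracellular cAMP when it starves. AX2, the wild type, was compared with null mutants of chdA, chdB and chdC, which encode CHD proteins, chromatin remodelers that use ATP to move nucleosomes. Each of the 4 strains was sampled while growing in axenic medium (0 h) and after 5 h of cAMP pulses given every 6 min, and each of the 8 samples stood for 2 libraries. No sample without pulses was taken at 5 h. Effects of the pulses therefore cannot be told apart from those of leaving growth or of time. Values are scaled read counts, the mean of the 2 libraries of a group, given with the SD over the 2 libraries where a value could be divided between them. The scaled counts summed to 46.2 M and 46.98 M in AX2 at 0 h and 5 h, to 31.2 M and 35.2 M in chdA-null, to 35.3 M and 38.8 M in chdB-null and to 33.0 M and 35.0 M in chdC-null (M, 1e6). The genes whose values could be divided, 90.0% to 99.4% of those in a sample, held between 6.56 M (chdA-null at 5 h) and 30.5 M reads (AX2 at 5 h) per library. The p-values on the split libraries measure only the spread between the 2 libraries of a group, pooled per gene over the 8 groups. The labels do not say whether these libraries came from separate cultures. The typical SD of log2 values between the 2 libraries ranged from 0.093 in growing chdB-null to 0.373 in chdB-null at 5 h. The pooled spread may therefore give p-values that are too small for groups that vary more. In a principal component analysis of the 16 libraries, component 1 held 77.7% of the variance and parted 5 h from 0 h. Component 2, with 8.04%, set the chdC-null libraries of both stages apart.

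The first question was whether the disrupted genes still gave transcripts. Each gene was low in its own mutant at both stages. chdA (DDB_G0284171) stood at 2524 ± 3.01 in growing AX2 and 403 ± 1.99 in chdA-null (15.98% of AX2, limma log2 -2.63 ± 0.21, adjusted p = 2.0e-07), and at 5 h at 4315 ± 743 and 579 ± 52.8 (13.4%, adjusted p = 1.7e-06). In chdB-null it was 2656 ± 27.0 at 0 h and 3335 ± 1174 at 5 h, and in chdC-null 2797 ± 174 and 3919.7 ± 587. chdB (DDB_G0280705) was the least reduced at 0 h, with 536 ± 33.2 in chdB-null against 1484 ± 213 in AX2 (36.1%, log2 -1.45 ± 0.29, adjusted p = 0.0022), and at 5 h it was 50.2 ± 30.98 against 905 ± 73.2 (5.55%, adjusted p = 2.2e-07). It was 1146 ± 103 and 1203 ± 118 in chdA-null, and 1936 ± 359 and 1108 ± 179 in chdC-null, at 0 h and 5 h. chdC (DDB_G0293012) rose in AX2 from 3632 ± 99.4 to 17156 ± 3151 (log2 2.23 ± 0.18, adjusted p = 4.7e-08), whereas chdC-null held 329 ± 23.0 at 0 h (9.05%, adjusted p = 1.6e-08) and 618 ± 137 at 5 h (3.61%, adjusted p = 7.2e-10). At 0 h it was 3509 ± 118 in chdA-null and 3589.9 ± 49.7 in chdB-null. At 5 h it was also below AX2 in chdA-null (10746, 62.6%, adjusted p = 0.033) and chdB-null (10581, 61.7%, adjusted p = 0.020). Each of these mutant levels is 1 undivided value, so its p rests on the spread of the other groups. Both calls ended at equal totals (adjusted p = 0.39 and 0.15), and that of chdB-null also under TMM scaling (adjusted p = 0.13). The 3 identifiers were written down from general knowledge of the genes, because the reference pairs them with no symbol.

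In AX2, genes of the cAMP relay, tiger genes and proteasome genes rose over 5 h of cAMP pulses, and ribosomal protein, lysosome and DNA replication genes fell. acaA, the adenylyl cyclase of aggregation, rose from 32.8 ± 1.47 to 29261 ± 3198 (log2 9.59 ± 0.19), and the cAMP receptor genes carA-1 (log2 7.51 ± 0.19) and carC (log2 8.59 ± 0.33) and regA, an intracellular cAMP phosphodiesterase (log2 5.47 ± 0.16), rose with it. Of the 19 measured cAMP relay genes, 18 rose and 0 fell, with a median log2 of 2.95 relative to all genes (camera adjusted p = 1.1e-05, and adjusted p = 0.11 with an estimated correlation). Estimated over the 5 members divided in all groups, a choice made after seeing the data, the correlation gave camera adjusted p = 2.4e-05. The genes with the largest rises were cbpC (DDB_G0283613), a calcium-binding protein, from 1.49 ± 2.11 to 49737 ± 610.2 (log2 12.94 ± 0.34), and tgrC1 (DDB_G0280531), a surface protein of cell adhesion and kin recognition, from 1.99 ± 0.00372 to 50100.5 ± 252 (log2 12.81 ± 0.38). psiI (12.41 ± 0.25), tgrR1 (12.15 ± 0.24), act31 (11.79 ± 0.34), comD (11.65 ± 0.24), cbpA (11.63 ± 0.49) and gppA (11.22 ± 0.32) followed, in log2 ± SE. The largest falls were those of fscJ (DDB_G0292102), a frizzled-like receptor gene, from 3149 ± 265 to 5.65 ± 6.66 (log2 -8.37 ± 0.42), and the calcium-upregulated gene cupF (log2 -8.20 ± 0.19). gp130 (-8.14 ± 0.28), acly (-8.14 ± 0.28), an ATP citrate lyase gene, the calcium-upregulated gene cupC (-7.97 ± 0.18), pyr56 (-7.90 ± 0.24) of pyrimidine synthesis, and the polyketide synthase genes pks16 (-7.84 ± 0.28) and pks17 (-7.82 ± 0.31) came next. Among the genes named here, the largest adjusted p was 0.00017 (limma).

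Among the other lists in AX2, 20 of 22 measured tiger genes, a family of adhesion and recognition proteins, rose and 2 fell. Their median log2 was 3.77 relative to all genes (camera adjusted p = 2.0e-05, and adjusted p = 0.098 with an estimated correlation). Estimated over the 19 members divided in all groups, the correlation gave camera adjusted p = 0.020. tgrI1 was 5138 ± 703 at 5 h and was listed at 0 in both 0 h libraries. Proteasome genes rose, 37 of 40 with 0 falling, such as psmE4 (2.57 ± 0.22) and psmD1 (2.48 ± 0.18). The list median was 1.64 relative to all genes (camera adjusted p = 4.5e-06, and adjusted p = 0.42 with an estimated correlation). Of 74 transcription factors 51 rose and 12 fell, led by gbfA, the G-box binding factor (log2 7.76 ± 0.22), and srfA, a factor related to serum response factor (log2 6.76 ± 0.28). Relative to all genes, their median was 0.94 (camera adjusted p = 0.0027, and adjusted p = 0.48 with an estimated correlation). Autophagy genes rose in 10 cases of 12 and fell in 1, with atg8 (3.27 ± 0.19) and atg1 (3.22 ± 0.19) among them. The median of the list, relative to all genes, was 1.86 (camera adjusted p = 0.012, and adjusted p = 0.28 with an estimated correlation). Ribosomal protein genes fell, 74 of 76 with 0 rising, for example rps12 (-2.51 ± 0.20) and rpl21 (-2.47 ± 0.20). Together they had a median log2 of -1.63 relative to all genes (camera adjusted p = 1.7e-08, and adjusted p = 0.51 with an estimated correlation). Lysosome and endocytosis genes fell in 20 cases of 26 and rose in 3, led by ctsD, the cathepsin D gene (log2 -5.77 ± 0.29), and cprG, a cysteine proteinase gene (log2 -4.49 ± 0.25). As a group, they lay at a median of -2.69 relative to all genes (camera adjusted p = 8.2e-05, and adjusted p = 0.42 with an estimated correlation). DNA replication genes fell in 22 cases of 26 and rose in 2, among them polA3 (-4.84 ± 0.25) and mcm4 (-3.74 ± 0.30). The group median was -2.26 relative to all genes (camera adjusted p = 8.4e-05, and adjusted p = 0.42 with an estimated correlation).

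The remaining 11 lists passed no camera test in AX2. Cell division genes were 2 higher and 12 lower of 15, with the cyclin gene cycD rising (log2 4.83 ± 0.19) and smc4 falling (log2 -2.95 ± 0.33). The 6 adhesion genes gave 3 higher, tgrC1, tgrB1 (log2 9.44 ± 0.30) and csaA, the contact site A glycoprotein gene (log2 9.10 ± 0.28), and 2 lower. Starvation and density sensing gave 5 higher and 8 lower of 16, with the GATA factor gene gtaC rising (log2 4.62 ± 0.24) and ctnA, which encodes countin (log2 -5.26 ± 0.26), and aprA, a secreted repressor of proliferation (log2 -3.47 ± 0.26), falling. Prestalk markers gave 8 higher and 3 lower of 12, including cprB (8.17 ± 0.32) and rasD (6.39 ± 0.32), and prespore markers 3 and 3 of 10, with cotA (2.14 ± 0.30) and spiA (-2.12 ± 0.26). The actin cytoskeleton and chemotaxis list gave 20 higher and 9 lower of 40, including the formin gene forC (log2 5.56 ± 0.21) and the myosin gene myoA (log2 3.96 ± 0.15). Actin genes gave 8 higher and 2 lower of 32, such as act24 (4.32 ± 0.18) and act33 (-1.69 ± 0.32), and their median log2 of -0.08 and mean of 0.71 differed in sign. Heat shock genes gave 15 higher and 5 lower of 24, with hspF-1 (5.54 ± 0.26) and hspK (-4.63 ± 0.22), and polyketide synthases 22 and 8 of 37, with pks26 (6.23 ± 0.32) and pks42 (5.50 ± 0.33). Histones gave 4 higher and 4 lower of 12, with H3v1 (-1.91 ± 0.25) and H2Bv2 (1.80 ± 0.18), and chromatin regulators 7 and 7 of 14, with agnA (-2.81 ± 0.18) and sir2A (2.24 ± 0.16). Adjusted over the list alone, the counts were equal to those over all genes for every list in AX2 except heat shock proteins, with 16 higher and 5 lower. Over all genes in AX2, limma called 4486 higher and 3637 lower of 9982 tested, and 3575 were at least 2-fold higher and 2828 at least 2-fold lower of 9437 compared without a test. The 2 libraries of each stage lay apart in the direction of the change for 7942 of the 7956 called genes with both values divided, which a call on the same libraries selects for (chance gives 33.3% of genes not so selected).

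The change common to the 4 strains was tested in a model with additive effects of stage and strain, with 1 value per sample. psiI had the largest rise, 115698 ± 67870.0 against 50.2 ± 27.3 (mean and SD over the 4 strains, 5 h against 0 h, log2 10.93 ± 0.38, adjusted p = 2.2e-07), followed by cbpC (10.90 ± 0.51), tgrC1 (10.73 ± 0.58), tgrR1 (10.54 ± 0.48), comD (10.35 ± 0.38), gppA (9.94 ± 0.46), act31 (9.82 ± 0.54) and fnkD-1 (9.51 ± 0.37). gp130 had the largest fall (log2 -7.88 ± 0.30, adjusted p = 2.2e-07), followed by acly (-6.83 ± 0.52), pyr4 (-6.67 ± 0.36), pks17 (-6.51 ± 0.40), pks16 (-6.50 ± 0.40), pyr56 (-6.40 ± 0.39), pssA (-6.21 ± 0.32) and plbE (-5.95 ± 0.44). limma called 3439 genes higher and 3161 lower at 5 h. In the single strains, limma called 4488 higher and 3343 lower in chdA-null, 3123 and 4289 in chdB-null, and 3811 and 3611 in chdC-null, and the counts at 2-fold were 3380 and 2513, 2118 and 3169, and 2661 and 2619. The cAMP relay genes rose in every mutant, 18 of 19 in chdA-null, 18 in chdB-null and 18 in chdC-null (camera adjusted p = 5.1e-06, 1.1e-07 and 5.3e-07). In the same order, these became adjusted p = 0.11, 0.073 and 0.084 with an estimated correlation. Estimated over the members divided in all groups, the correlation gave camera adjusted p = 1.2e-05, 3.0e-07 and 1.2e-06. tgrC1 reached 18764 in chdA-null (log2 11.16 ± 0.46), 24026 in chdB-null (log2 10.75 ± 0.46) and 9428 ± 5600.5 in chdC-null (log2 8.16 ± 0.38), against 50100.5 ± 252 in AX2. Among the largest falls were aifC (log2 -7.05 ± 0.31) and rhgA (log2 -6.33 ± 0.18) in chdA-null, plbE (log2 -5.66 ± 0.21) in chdB-null, and thyA, a thymidylate synthase gene (log2 -5.13 ± 0.23), and ponB, of the ponticulin family (log2 -5.25 ± 0.41), in chdC-null. Across genes, which are not independent replicates, the slope of a mutant's change on that of AX2 was 0.763 in chdA-null, 0.703 in chdB-null and 0.656 in chdC-null by least squares. With the change of the other 2 mutants as an instrument, the slopes were 0.816, 0.734 and 0.702.

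**Figure D1:**
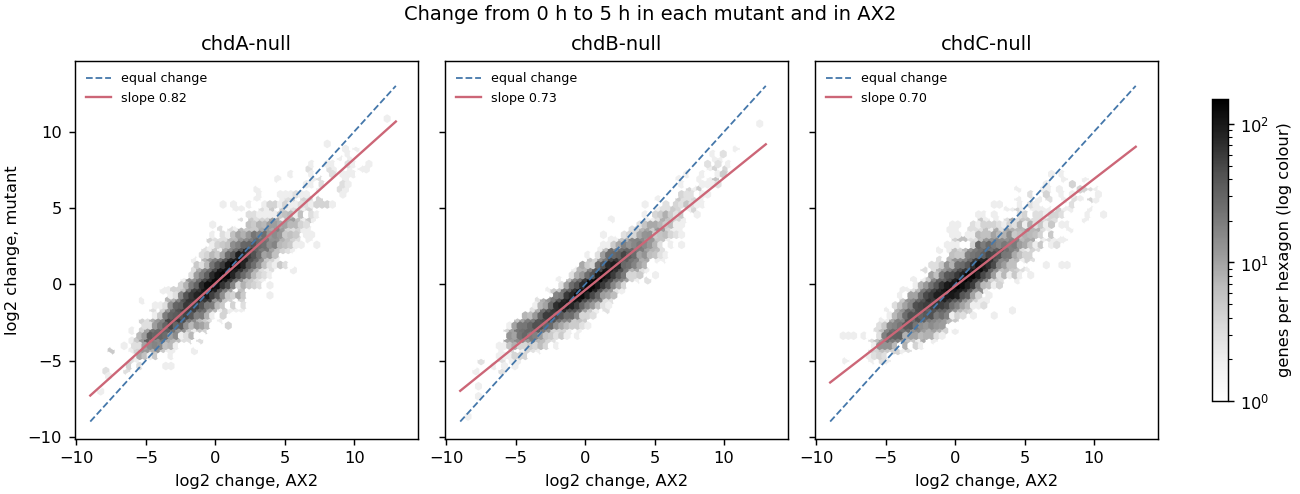
Log2 change from 0 h to 5 h of 9982 genes in each mutant (vertical) against the change in AX2 (horizontal), shaded by genes per hexagon, with the line of equal change (dashed) and the slope fitted with the change of the other 2 mutants as an instrument. The slopes of 0.816, 0.734 and 0.702 lie below the line of equal change.

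Growing chdA-null cells were compared with growing AX2 to find what loss of chdA altered before development. Relative to all genes, the actin, actin cytoskeleton and ribosomal protein lists had a lower median and the heat shock list a higher one. dcd2B (DDB_G0268374) was highest over AX2, 1612 ± 147 against 31.3 ± 2.05 (log2 5.47 ± 0.29), followed by cprC, a cysteine proteinase gene, at 746 ± 58.8 against 20.4 ± 4.88 (log2 4.90 ± 0.33), and sigB at 1385 ± 50.6 against 51.2 ± 3.42 (log2 4.63 ± 0.18). cnrJ (4.01 ± 0.28), stkA (3.84 ± 0.29), a GATA factor gene of spore formation, symA (3.53 ± 0.30), fslM-1 (3.45 ± 0.36) and hspJ (3.45 ± 0.49) completed the 8 largest. fscJ fell furthest below AX2, 12.3 ± 4.19 against 3149 ± 265 (log2 -7.53 ± 0.42), with the related receptor genes fslK (-5.75 ± 0.24) and fslB (-4.40 ± 0.28), and ponB (DDB_G0286247) was 20.9 ± 5.43 against 1181 ± 140.0 (log2 -5.53 ± 0.41). rasW (-3.67 ± 0.18), chdh (-3.51 ± 0.25), pdiA (-3.36 ± 0.23), the inhibitor of the secreted cAMP phosphodiesterase, and vinA (-3.15 ± 0.22) were also lower. Of 32 actin genes 24 were lower and 3 higher, with act7 and act1 lower (log2 -1.98 ± 0.21 and -1.97 ± 0.23) and act33 higher (log2 2.53 ± 0.32). Against all genes, the list had a median log2 of -1.66 (camera adjusted p = 1.4e-07, and adjusted p = 0.11 with an estimated correlation). The actin cytoskeleton and chemotaxis list gave 30 lower and 0 higher of 40, including limE (log2 -1.71 ± 0.17), the coronin gene corA (log2 -1.56 ± 0.24), the myosin light chain gene mlcE (log2 -1.52 ± 0.21) and abpC, a filamin gene (log2 -1.50 ± 0.24). Their median log2 was -0.79 relative to all genes (camera adjusted p = 1.9e-10, and adjusted p = 0.17 with an estimated correlation). Ribosomal protein genes gave 28 lower and 0 higher of 76, such as rpl13 (-1.25 ± 0.23). The list median was -0.59 relative to all genes (camera adjusted p = 4.7e-09, and adjusted p = 0.48 with an estimated correlation). Heat shock genes gave 15 higher and 1 lower of 24, with hspG12 (2.91 ± 0.42) and hspI (2.47 ± 0.25) beside hspJ. Relative to all genes, their median was 1.37 (camera adjusted p = 8.6e-05, and adjusted p = 0.34 with an estimated correlation). The lysosome list passed no camera test, with 9 higher and 4 lower of 26, and held the lysozyme genes alyC (3.26 ± 0.28) and alyB (2.53 ± 0.27) above AX2 and manA, an alpha-mannosidase gene, below it (log2 -2.51 ± 0.23). Every gene named for this comparison had an adjusted p of at most 0.0043. At equal totals, higher and lower counts in chdA-null became 2 and 12 for the actin cytoskeleton list, 0 and 6 for ribosomal proteins and 17 and 3 for the lysosome list. Adjusted over the list alone, the counts were equal for the actin cytoskeleton list, the heat shock proteins and the lysosome list, but 4 higher and 25 lower for the actin genes and 0 higher and 37 lower for the ribosomal proteins.

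Over all genes, limma called 1378 higher and 1149 lower in growing chdA-null (54.5% higher). Without a test, 700 of 8764 genes were at least 2-fold higher and 559 at least 2-fold lower. Scaling all libraries to equal totals moved the median log2 of all genes from -0.01 to 0.52 and gave 4472 higher and 472 lower (90.5% higher), and 1773 and 249 at 2-fold. The count of 2527 fell to 1604 without chdA-null library 1 and to 1643 without chdA-null library 2.

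The question for growing chdB-null cells was which transcripts loss of chdB altered. The heat shock list had a higher median, and the actin and ribosomal protein lists a lower one, relative to all genes. racF2 (DDB_G0276967), a Rac GTPase gene, was 173 ± 13.8 against 1.99 ± 1.40 (log2 4.68 ± 0.34), and 3B-1 (DDB_G0272795) was 3066 ± 175 against 120.3 ± 5.40 (log2 4.61 ± 0.18). hspG1 (4.56 ± 0.54), cprB (4.10 ± 0.32), a cysteine proteinase gene of prestalk cells, the Ras genes rasZ (3.63 ± 0.28) and rasU (3.50 ± 0.39), hspJ (3.62 ± 0.49) and hspG12 (3.52 ± 0.42) were the other large rises. gefJ (DDB_G0277913), a Ras exchange factor gene, was the lowest against AX2, 37.9 ± 5.44 against 781 ± 48.6 (log2 -4.20 ± 0.21), followed by vwkA, an alpha kinase gene, 524 ± 60.9 against 5905 ± 250.1 (log2 -3.49 ± 0.15). samkB (-2.61 ± 0.23), the calcium-upregulated genes cupH (-2.42 ± 0.17), cupG (-2.41 ± 0.18) and cupC (-2.33 ± 0.18), racQ (-2.31 ± 0.35) and the Argonaute gene agnB (-2.29 ± 0.15) were also lower. Of 32 actin genes 22 were lower and 3 higher, including act10 (-1.40 ± 0.24) and act16 (-1.37 ± 0.24), with act31 (2.48 ± 0.34) higher. The median of the list, relative to all genes, was -1.35 (camera adjusted p = 5.0e-12, and adjusted p = 0.049 with an estimated correlation). This was the only camera call on the split libraries, over all comparisons, that held with a correlation estimated over all members. Over the members divided in all groups, a choice made after seeing the data, 21 of 221 list shifts passed, with adjusted p = 0.035 for these actin genes with that estimated correlation. Against AX2 in growth, the actin cytoskeleton in chdA-null (camera adjusted p = 0.044) and starvation and lysosome genes in chdC-null (0.029 and 0.030) passed too. At 5 h, cAMP relay and lysosome genes in chdB-null (camera adjusted p = 0.0065 and 0.044) and tiger genes in chdA-null and chdC-null (0.030 and 0.041) passed. For starvation the estimate rested on 3 of 16 members. Heat shock genes in growing chdB-null gave 14 higher and 1 lower of 24, with hspG5 (3.33 ± 0.40) among them. Together they had a median log2 of 2.06 relative to all genes (camera adjusted p = 6.9e-06, and adjusted p = 0.28 with an estimated correlation). Ribosomal protein genes gave 0 higher and 20 lower of 76, such as rpl8 (-1.21 ± 0.24). As a group, they lay at a median of -0.61 relative to all genes (camera adjusted p = 2.4e-16, and adjusted p = 0.28 with an estimated correlation). Tiger genes gave 7 higher and 0 lower of 22, such as tgrK1 (1.93 ± 0.33) and tgrC2 (1.54 ± 0.28). The group median was 0.58 relative to all genes (camera adjusted p = 0.034, and adjusted p = 0.42 with an estimated correlation), and the call ended at equal totals (camera adjusted p = 0.69).

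Other lists in growing chdB-null shifted less. The actin cytoskeleton list, with 8 lower and 0 higher of 40, such as the coronin gene corA (log2 -0.99 ± 0.24, adjusted p = 0.076 at equal totals), had a median of -0.51 relative to all genes (camera adjusted p = 3.9e-08, and adjusted p = 0.27 with an estimated correlation). The starvation list, with 1 higher and 1 lower, countin gene ctnA (log2 -1.45 ± 0.30), of 16, lay at -0.44 (camera adjusted p = 0.0015, and adjusted p = 0.28 with an estimated correlation), percentile 6.01 among random lists matched on expression. The lysosome list, with 3 higher, cprE (1.65 ± 0.37), p80 (1.28 ± 0.25) and alyL (1.19 ± 0.23), and 1 lower, alyA (-1.19 ± 0.29), of 26, lay at -0.40 (camera adjusted p = 0.018, and adjusted p = 0.68 with an estimated correlation). The transcription factors, with 5 higher, led by the GATA factor gene gtaR (log2 2.46 ± 0.25), and 2 lower of 74, lay at -0.16 (camera adjusted p = 0.044, and adjusted p = 0.68 with an estimated correlation), and the call ended at equal totals (camera adjusted p = 0.25). Their median of 0.00 and their mean of 0.05, not taken relative to all genes, differed in sign. Prespore markers, with 0 higher and 1 lower, pspD (-1.56 ± 0.24), of 10, lay at -0.38 (camera adjusted p = 0.022, and adjusted p = 0.32 with an estimated correlation), and the call ended under TMM scaling (camera adjusted p = 0.052). No histone gene of 12 passed limma, 5 had an unadjusted p under 0.05, and the list had a median of -0.55 relative to all genes (camera adjusted p = 0.0079, and adjusted p = 0.48 with an estimated correlation). Equal totals raised the median of all genes from 0.16 to 0.53, and with it the medians of the actin cytoskeleton, starvation, lysosome, transcription factor and prespore lists from -0.35, -0.28, -0.24, 0.00 and -0.22 to 0.04, 0.10, 0.14, 0.36 and 0.14. Against all genes, camera still passed there for the actin cytoskeleton, starvation, lysosome and prespore lists (camera adjusted p = 4.9e-07, 0.0019, 0.0071 and 0.0032). Among the genes named here, the largest adjusted p was 0.032. Under TMM scaling, higher and lower counts in chdB-null became 4 and 0 for tiger genes, 0 and 17 for the actin cytoskeleton list, 0 and 4 for the starvation list, 3 and 6 for the lysosome list, 4 and 8 for transcription factors, 0 and 2 for prespore markers and 0 and 3 for histones. At equal totals, higher and lower counts in chdB-null became 0 and 8 for ribosomal proteins, 14 and 0 for tiger genes, 7 and 1 for the actin cytoskeleton list, 8 and 1 for the lysosome list and 26 and 1 for transcription factors. Adjusted over the list alone, the counts were equal for the starvation list, the transcription factors, the prespore markers and the histones, but 3 higher and 24 lower for the actin genes, 15 higher and 2 lower for the heat shock proteins, 0 higher and 27 lower for the ribosomal proteins, 12 higher and 0 lower for the tiger genes, 0 higher and 11 lower for the actin cytoskeleton list and 3 higher and 6 lower for the lysosome list.

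Over all genes in growing chdB-null, limma called 1313 higher and 338 lower (79.5% higher), 917 and 638 under TMM scaling (59.0%), and 4469 and 193 at equal totals (95.9%). The median log2 of all genes was 0.16, -0.02 and 0.53 under the 3 scalings. Of 8860 genes compared without a test, 749 were at least 2-fold higher and 190 at least 2-fold lower, against 520 and 291 under TMM scaling and 1398 and 92 at equal totals. In chdB-null library 2 the 2 genes of the signal recognition particle RNA stood 6.95 log2 above library 1. The count of 1651 was 1038 without AX2 library 2, 938 without chdB-null library 1, 914 without chdB-null library 2, and 1008 when that library and 2 others that stood apart were left out together.

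Growing chdC-null cells were compared with growing AX2 for what loss of chdC altered before development. The lysosome, ribosomal protein and starvation lists had a lower median relative to all genes, and the largest rises included 5 copies of ponC, which were not among the fixed lists and were not tested as a group. The ponticulin-related gene ponC4 (DDB_G0286719) was 30193 against 39.3 ± 4.99 (log2 9.42 ± 0.54), with ponC1 (8.98 ± 0.45), ponC2 (8.70 ± 0.45), ponC5 (8.66 ± 0.47) and ponC3 (8.21 ± 0.41) close behind, although reads cannot be well divided among such similar copies. colA, which encodes colossin A, was 3765 ± 477 against 17.4 ± 9.17 (log2 7.45 ± 0.33), the cysteine proteinase gene cprA was 4779 ± 1446 against 128 ± 41.7 (log2 5.17 ± 0.25), and rnu1d, a U1 small nuclear RNA gene, was 489 ± 218 against 11.4 ± 2.13 (log2 4.84 ± 0.37). The receptor gene fslK (DDB_G0284729) fell furthest below AX2, 14.2 ± 2.19 against 644 ± 8.94 (log2 -5.08 ± 0.24), and fscJ was 199 ± 8.08 against 3149 ± 265 (log2 -3.95 ± 0.42). egeA (-3.68 ± 0.22), lmcB (-3.60 ± 0.23), DD7-1 (-3.54 ± 0.30), lmcA (-3.48 ± 0.23), alyD-1 (-3.20 ± 0.41) and fslB (-3.17 ± 0.28) were also lower. Of 26 lysosome and endocytosis genes 14 were lower and 0 higher, including the lysozyme genes alyB (-2.09 ± 0.27) and alyA (-1.94 ± 0.29). Against all genes, the list had a median log2 of -1.14 (camera adjusted p = 7.2e-09, and adjusted p = 0.19 with an estimated correlation). Ribosomal protein genes gave 34 lower and 0 higher of 76, such as rpl15-1 (-1.43 ± 0.23) and rps29 (-1.22 ± 0.25). Their median log2 was -0.80 relative to all genes (camera adjusted p = 2.1e-14, and adjusted p = 0.32 with an estimated correlation). The starvation list gave 7 lower and 1 higher of 16, with the counting factor genes cf45-1 (-2.93 ± 0.25) and cf60 (-2.24 ± 0.24) and the discoidin gene dscC-1 (log2 -2.46 ± 0.30) lower. The list median was -0.66 relative to all genes (camera adjusted p = 0.00024, and adjusted p = 0.22 with an estimated correlation), at percentile 3.53 among the random lists. Actin genes gave 23 lower and 3 higher of 32, with act28 (-2.31 ± 0.29) and act27 (-1.91 ± 0.34). Relative to all genes, their median was -0.99 (camera adjusted p = 3.2e-07, and adjusted p = 0.11 with an estimated correlation). The actin cytoskeleton list, with 11 lower, such as the profilin genes proB (-1.30 ± 0.24) and proA (-1.28 ± 0.26), and 1 higher, had a median of -0.30 relative to all genes (camera adjusted p = 0.0011, and adjusted p = 0.54 with an estimated correlation), but stood at percentile 59.9 among random lists matched on expression. Its own median of -0.18 became 0.30 at equal totals, as that of all genes rose from 0.11 to 0.58, and the call held (camera adjusted p = 0.023). Transcription factors gave 21 higher and 3 lower of 74, with the GATA factor genes gtaV (2.17 ± 0.21), gtaG (2.11 ± 0.27) and gtaT (-2.87 ± 0.28). The median of the list, relative to all genes, was 0.22 (camera adjusted p = 0.0042, and adjusted p = 0.52 with an estimated correlation). Tiger genes gave 8 higher and 0 lower of 22, among them tgrR1 (2.18 ± 0.24) and tgrC1 (2.09 ± 0.38). Together they had a median log2 of 0.60 relative to all genes (camera adjusted p = 0.029, and adjusted p = 0.42 with an estimated correlation), and the call ended at equal totals (camera adjusted p = 0.53). Every gene named for this comparison had an adjusted p of at most 0.0072. At equal totals, higher and lower counts in chdC-null became 0 and 6 for ribosomal proteins, 4 and 4 for actin genes, 10 and 2 for the actin cytoskeleton list and 63 and 1 for transcription factors. Adjusted over the list alone, the counts were equal for the starvation list, the actin cytoskeleton list and the transcription factors, but 0 higher and 16 lower for the lysosome list, 0 higher and 58 lower for the ribosomal proteins, 3 higher and 26 lower for the actin genes and 10 higher and 0 lower for the tiger genes.

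Over all genes in growing chdC-null, limma called 1754 higher and 1107 lower (61.3% higher), 1301 and 1631 under TMM scaling (44.4%), and 5063 and 438 at equal totals (92.0%), with a median log2 of all genes of 0.11, -0.05 and 0.58. Of 8914 genes compared without a test, 853 were at least 2-fold higher and 500 at least 2-fold lower, against 656 and 772 under TMM scaling and 1932 and 228 at equal totals. Relative to AX2, the longest of 5 length bins of genes lay 0.67 log2 above the shortest in chdC-null library 1 and 0.20 in library 2. The count of 2861 was 1894 without AX2 library 2, 1771 without chdC-null library 1, and 1715 when that library and 2 others that stood apart were left out together.

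After 5 h of cAMP pulses, the mutants were compared with AX2 for their early development. In chdA-null, relative to all genes, the proteasome, tiger and actin cytoskeleton lists had a lower median and the lysosome list a higher one. racF2 was 544 ± 24.6 against 59.7 ± 32.2 (log2 3.18 ± 0.34), cpras2 25119.6 against 3089 ± 779.5 (log2 3.04 ± 0.36) and abcA8, an ABC transporter gene, 3176 ± 1.78 against 587 ± 0.0874 (log2 2.43 ± 0.21). rasU (2.84 ± 0.39), fnkA (2.69 ± 0.22), the Rac gene rac1B (2.55 ± 0.27), cnrO (2.50 ± 0.30) and abpF (2.49 ± 0.21) were also higher. 5NT (DDB_G0287199), a nucleotidase gene, fell furthest below AX2, 146 ± 45.6 against 3183 ± 427 (log2 -4.43 ± 0.43), and psiA (DDB_G0291982), a secreted factor that induces prespore cells, was 323 ± 50.8 against 6010.3 ± 1822 (log2 -4.17 ± 0.37). gacII (-3.94 ± 0.40), a RhoGAP gene, csbA (-3.49 ± 0.34), tgrO3 (-3.34 ± 0.32), adcF (-3.26 ± 0.61), mcfR (-3.17 ± 0.39) and limA (-2.92 ± 0.32) were also lower. Of 40 proteasome genes 31 were lower and 0 higher, such as psmB6 (-1.19 ± 0.22) and psmC1 (-1.12 ± 0.25). As a group, they lay at a median of -0.89 relative to all genes (camera adjusted p = 2.5e-09, and adjusted p = 0.28 with an estimated correlation). Tiger genes gave 12 lower and 1 higher of 22, with tgrI3 (-2.50 ± 0.39) and tgrI1 (-2.28 ± 0.37). The group median was -1.17 relative to all genes (camera adjusted p = 8.6e-05, and adjusted p = 0.11 with an estimated correlation). Lysosome genes gave 13 higher and 2 lower of 26, with the vacuolin genes vacA (2.06 ± 0.25) and vacB (2.06 ± 0.27). Against all genes, the list had a median log2 of 0.68 (camera adjusted p = 0.0016, and adjusted p = 0.54 with an estimated correlation). The actin cytoskeleton list gave 20 lower and 2 higher of 40, including limD (-1.96 ± 0.23) and the talin gene talB (log2 -1.26 ± 0.24). Their median log2 was -0.51 relative to all genes (camera adjusted p = 6.8e-05, and adjusted p = 0.42 with an estimated correlation). Actin genes gave 20 lower and 6 higher of 32, with act32 (2.10 ± 0.30) higher. The list median was -0.85 relative to all genes (camera adjusted p = 0.021, and adjusted p = 0.54 with an estimated correlation). Cell division genes gave 6 lower and 0 higher of 15, with the aurora kinase gene aurK (log2 -1.40 ± 0.29) and cycD (log2 -1.20 ± 0.19) lower, and a median of -0.36 relative to all genes (camera adjusted p = 0.013, and adjusted p = 0.68 with an estimated correlation). Their own median of -0.35 became 0.06 at equal totals, as that of all genes rose from 0.01 to 0.41, and the call held (camera adjusted p = 0.0055). The cAMP relay list gave 6 lower and 0 higher of 19, with carC (log2 -1.70 ± 0.33) and pdsA, the secreted phosphodiesterase gene (log2 -1.08 ± 0.27, adjusted p = 0.069 at equal totals), lower. It had a median of -0.39 relative to all genes (camera adjusted p = 0.039, and adjusted p = 0.53 with an estimated correlation), at percentile 5.96 among the random lists. With the same rise of all genes at equal totals its own median went from -0.37 to 0.05, and the call ended (camera adjusted p = 0.069). Among the genes named here, the largest adjusted p was 0.011. At equal totals, higher and lower counts in chdA-null became 2 and 8 for the proteasome, 5 and 8 for the actin cytoskeleton list, 8 and 0 for actin genes, 1 and 2 for cell division and 3 and 1 for the cAMP relay. At 5 h, adjusted over the list alone, the counts were equal for the actin cytoskeleton list, cell division and the cAMP relay, but 0 higher and 34 lower for the proteasome, 1 higher and 14 lower for the tiger genes, 14 higher and 2 lower for the lysosome list and 6 higher and 21 lower for the actin genes.

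Over all genes in chdA-null at 5 h, limma called 1920 higher and 1563 lower (55.1% higher), and 3821 and 624 at equal totals (86.0%), where the median log2 of all genes went from 0.01 to 0.41. Without a test, 840 of 8889 genes were at least 2-fold higher and 708 at least 2-fold lower, and 1844 and 346 at equal totals. The count of 3483 was 2153 without AX2 library 2 of 5 h. Only 90.0% of the genes of this sample could be divided between its libraries.

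In chdB-null at 5 h, relative to all genes, the cAMP relay, proteasome, tiger and autophagy lists had a lower median, and the lysosome and DNA replication lists a higher one. gefJ fell furthest below AX2 again, 8.06 ± 0.266 against 553 ± 94.0 (log2 -5.41 ± 0.21), followed by cbpH (DDB_G0288623), a calcium-binding protein gene, 1.47 ± 0.141 against 107 ± 20.1 (log2 -4.10 ± 0.28). CYP516B1 (-2.69 ± 0.27), a cytochrome P450 gene, hspF-1 (-2.59 ± 0.26), zfaA (-2.52 ± 0.31), psiA (-2.42 ± 0.37), pks26 (-2.42 ± 0.32) and dia1 (-2.29 ± 0.34) were also lower. emg1 (DDB_G0272732), of ribosome biogenesis, was 395 ± 114 against 46.2 ± 38.1 (log2 3.17 ± 0.38), and pyr56 was 433 ± 6.70 against 65.7 ± 19.8 (log2 2.66 ± 0.24). wdr89 (3.01 ± 0.28), cprE (2.87 ± 0.37), ddx24 (2.64 ± 0.36), a DEAD-box helicase gene, trmt61 (2.62 ± 0.20), a tRNA methyltransferase gene, and V4-7 (2.59 ± 0.33) were also higher, and nat9, listed at 0 in AX2, was 24.9 ± 7.06. Of 19 cAMP relay genes 16 were lower and 0 higher, including the receptor genes carD (-1.92 ± 0.23) and carA-1 (-1.09 ± 0.22) and the exchange factor gene gefA (log2 -1.13 ± 0.18). Relative to all genes, their median was -0.57 (camera adjusted p = 0.0013, and adjusted p = 0.28 with an estimated correlation). Proteasome genes gave 30 lower and 0 higher of 40, such as psmD13 (-1.12 ± 0.19). The median of the list, relative to all genes, was -0.47 (camera adjusted p = 0.0016, and adjusted p = 0.66 with an estimated correlation). Tiger genes gave 13 lower and 0 higher of 22, with tgrR2 (-1.99 ± 0.39) and tgrI1 (-1.56 ± 0.37). Together they had a median log2 of -0.54 relative to all genes (camera adjusted p = 0.029, and adjusted p = 0.42 with an estimated correlation). Autophagy genes gave 9 lower and 0 higher of 12, with atg9 (-1.22 ± 0.18) and atg1 (-1.15 ± 0.19). As a group, they lay at a median of -0.36 relative to all genes (camera adjusted p = 0.022, and adjusted p = 0.31 with an estimated correlation), at percentile 6.92 among the random lists. Lysosome genes gave 18 higher and 0 lower of 26, with the cysteine proteinase genes cprF (2.03 ± 0.34) and cprG (1.78 ± 0.25) beside cprE. The group median was 1.23 relative to all genes (camera adjusted p = 1.2e-07, and adjusted p = 0.26 with an estimated correlation). DNA replication genes gave 16 higher and 2 lower of 26, with polA3 (2.54 ± 0.25) and mcm6 (1.97 ± 0.31). Against all genes, the list had a median log2 of 1.12 (camera adjusted p = 3.6e-06, and adjusted p = 0.34 with an estimated correlation). Heat shock genes gave 11 higher and 3 lower of 24, with hspC (1.88 ± 0.18). Their median log2 was 1.01 relative to all genes (camera adjusted p = 0.010, and adjusted p = 0.58 with an estimated correlation). The ribosomal list gave 2 higher, rps4 (log2 0.85 ± 0.20) and rpl15-1 (log2 0.83 ± 0.20), and 0 lower of 76. The list median was 0.48 relative to all genes (camera adjusted p = 0.00010, and adjusted p = 0.68 with an estimated correlation). Every gene named for this comparison had an adjusted p of at most 0.0094. Under TMM scaling, higher and lower counts in chdB-null became 0 and 9 for the cAMP relay, 1 and 10 for the proteasome, 0 and 6 for tiger genes, 0 and 4 for autophagy and 11 and 0 for ribosomal proteins. At equal totals, higher and lower counts in chdB-null became 0 and 8 for the cAMP relay, 1 and 10 for the proteasome, 0 and 6 for tiger genes, 0 and 3 for autophagy and 20 and 0 for ribosomal proteins. At 5 h, adjusted over the list alone, the counts were equal for the proteasome, the lysosome list, DNA replication and the heat shock proteins, but 0 higher and 17 lower for the cAMP relay, 0 higher and 14 lower for the tiger genes, 0 higher and 10 lower for autophagy and 0 higher and 0 lower for the ribosomal proteins.

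Over all genes in chdB-null at 5 h, limma called 1520 higher and 3451 lower (30.6% higher), but 2138 and 1930 under TMM scaling (52.6%) and 2155 and 1887 at equal totals (53.3%), so which direction held more genes turned with the scaling. The median log2 of all genes was -0.29, -0.03 and -0.02. Of 8860 genes compared without a test, 678 were at least 2-fold higher and 1308 at least 2-fold lower, against 1028 and 741 under TMM scaling and 1033 and 683 at equal totals. Called in the same direction as deposited and under TMM scaling were 1520 higher and 1930 lower genes.

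In chdC-null at 5 h, the tiger, proteasome, actin cytoskeleton and cell division lists had a lower median relative to all genes, and the ponC copies again had the largest rises. ponC4 was 130139 against 1209.8 ± 445 (log2 6.79 ± 0.54), and ponC3, with the largest rise, 44889 against 277 ± 86.0 (log2 7.35 ± 0.50), followed by ponC1 (7.26 ± 0.55), ponC5 (7.18 ± 0.57) and ponC2 (7.09 ± 0.56). hlcs1 (DDB_G0288791) was 3090.2 ± 309 against 59.7 ± 3.48 (log2 5.58 ± 0.23), and the U1 RNA genes rnu1c (5.94 ± 0.41) and rnu1d (5.24 ± 0.37) were also higher. psiA was 48.0 ± 25.8 against 6010.3 ± 1822 (log2 -6.88 ± 0.37), cmbC 299 ± 151 against 16153 ± 4004 (log2 -5.80 ± 0.44) and the prestalk proteinase gene cprB 145 ± 50.2 against 7527 ± 1878 (log2 -5.67 ± 0.32). csbA (-5.77 ± 0.34), gacII (-5.66 ± 0.40), csbB (-5.52 ± 0.34), pks26 (-5.52 ± 0.32) and lmcB (-5.43 ± 0.23) were also lower. Of 22 tiger genes 15 were lower and 1 higher, with tgrO3 (-4.40 ± 0.32) and tgrI1 (-3.46 ± 0.37). Relative to all genes, their median was -2.06 (camera adjusted p = 0.00021, and adjusted p = 0.14 with an estimated correlation). Proteasome genes gave 35 lower and 0 higher of 40, such as psmB2 (-1.91 ± 0.20) and psmA7 (-1.41 ± 0.15). The median of the list, relative to all genes, was -0.99 (camera adjusted p = 9.1e-08, and adjusted p = 0.34 with an estimated correlation). The actin cytoskeleton list gave 25 lower and 2 higher of 40, with myoA (log2 -2.69 ± 0.15), limD (log2 -2.57 ± 0.23) and forC (log2 -2.04 ± 0.21) lower. Together they had a median log2 of -0.82 relative to all genes (camera adjusted p = 0.00016, and adjusted p = 0.47 with an estimated correlation). Actin genes gave 27 lower and 2 higher of 32, with act29 (-2.57 ± 0.27). As a group, they lay at a median of -0.80 relative to all genes (camera adjusted p = 0.0036, and adjusted p = 0.42 with an estimated correlation). Cell division genes gave 12 lower and 0 higher of 15, including aurK (-2.01 ± 0.29), cdc20 (-1.78 ± 0.25) and the polo kinase gene plk (log2 -1.57 ± 0.32). The group median was -1.10 relative to all genes (camera adjusted p = 0.0056, and adjusted p = 0.66 with an estimated correlation). Lysosome genes gave 13 higher and 2 lower of 26, with cprD (1.67 ± 0.23) and vacA (1.42 ± 0.20) higher and nagB (-1.85 ± 0.21) lower. Against all genes, the list had a median log2 of 0.67 (camera adjusted p = 0.015, and adjusted p = 0.66 with an estimated correlation). Heat shock genes gave 12 higher and 3 lower of 24, with hspK (3.05 ± 0.22). Their median log2 was 0.95 relative to all genes (camera adjusted p = 0.032, and adjusted p = 0.66 with an estimated correlation), and the call ended at equal totals (camera adjusted p = 0.063) and with low members left out. The ribosomal list gave 4 higher and 0 lower of 76, with rpl5 (0.70 ± 0.20). The list median was 0.31 relative to all genes (camera adjusted p = 0.046, and adjusted p = 0.83 with an estimated correlation), and the call ended under TMM scaling (camera adjusted p = 0.052). The cAMP relay list passed no camera test in chdC-null at 5 h, with 12 lower and 2 higher of 19 and a median of -0.67 relative to all genes (camera adjusted p = 0.074, and adjusted p = 0.59 with an estimated correlation). Of the 10 prespore markers, which passed no camera test, 5 were higher, among them the spore gene spiA (log2 2.01 ± 0.26) and the spore coat gene cotD (log2 1.72 ± 0.26), and 1 lower, cotB (log2 -1.28 ± 0.30). Among the genes named here, the largest adjusted p was 0.015. At equal totals, higher and lower counts in chdC-null became 4 and 9 for actin genes, 0 and 7 for cell division, 51 and 0 for ribosomal proteins, 3 and 6 for the cAMP relay and 8 and 1 for prespore markers. At 5 h, adjusted over the list alone, the counts were equal for the tiger genes, the proteasome, the actin cytoskeleton list, the actin genes, cell division, the lysosome list, the heat shock proteins, the cAMP relay and the prespore markers, but 0 higher and 0 lower for the ribosomal proteins.

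Over all genes in chdC-null at 5 h, limma called 2715 higher and 3258 lower (45.5% higher), and 4014 and 1879 at equal totals (68.1%), where the median log2 of all genes went from -0.10 to 0.31. Without a test, 1497 of 9152 genes were at least 2-fold higher and 1719 at least 2-fold lower, and 2366 and 872 at equal totals.

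**Figure D2:**
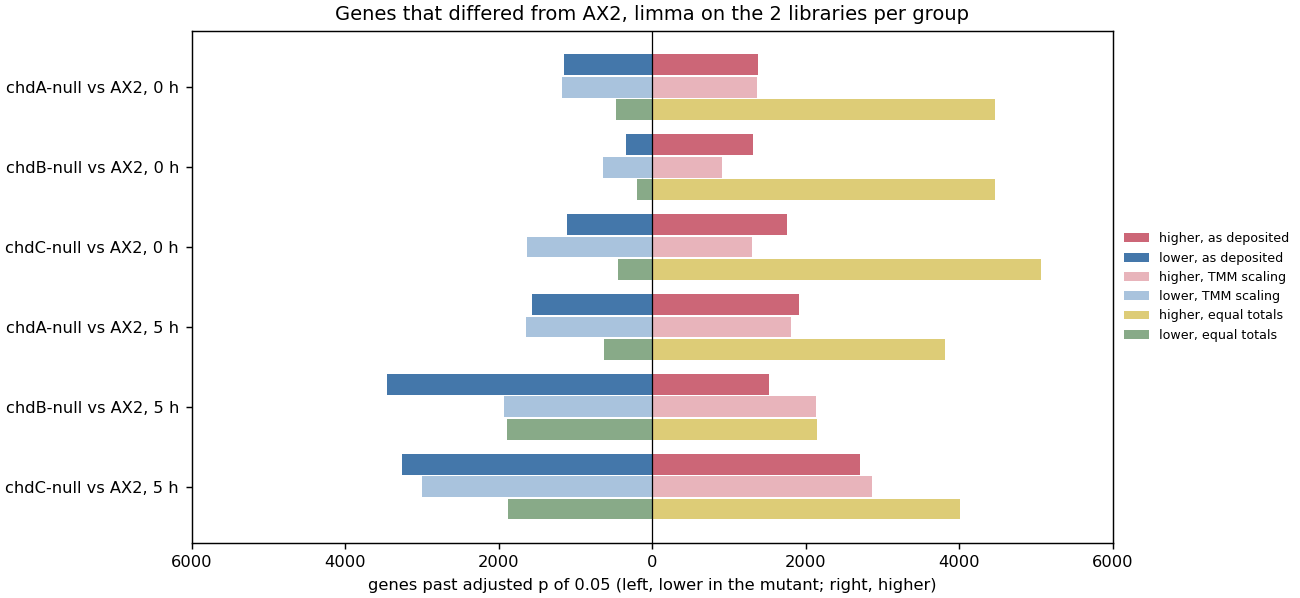
Number of genes past an adjusted p of 0.05 (limma, 2 libraries per group) that were lower (left) or higher (right) than AX2 in each mutant and stage, as deposited, under TMM scaling and at equal totals. At 5 h chdB-null had 3451 lower and 1520 higher genes as deposited, but 1887 and 2155 at equal totals.

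**Figure D3:**
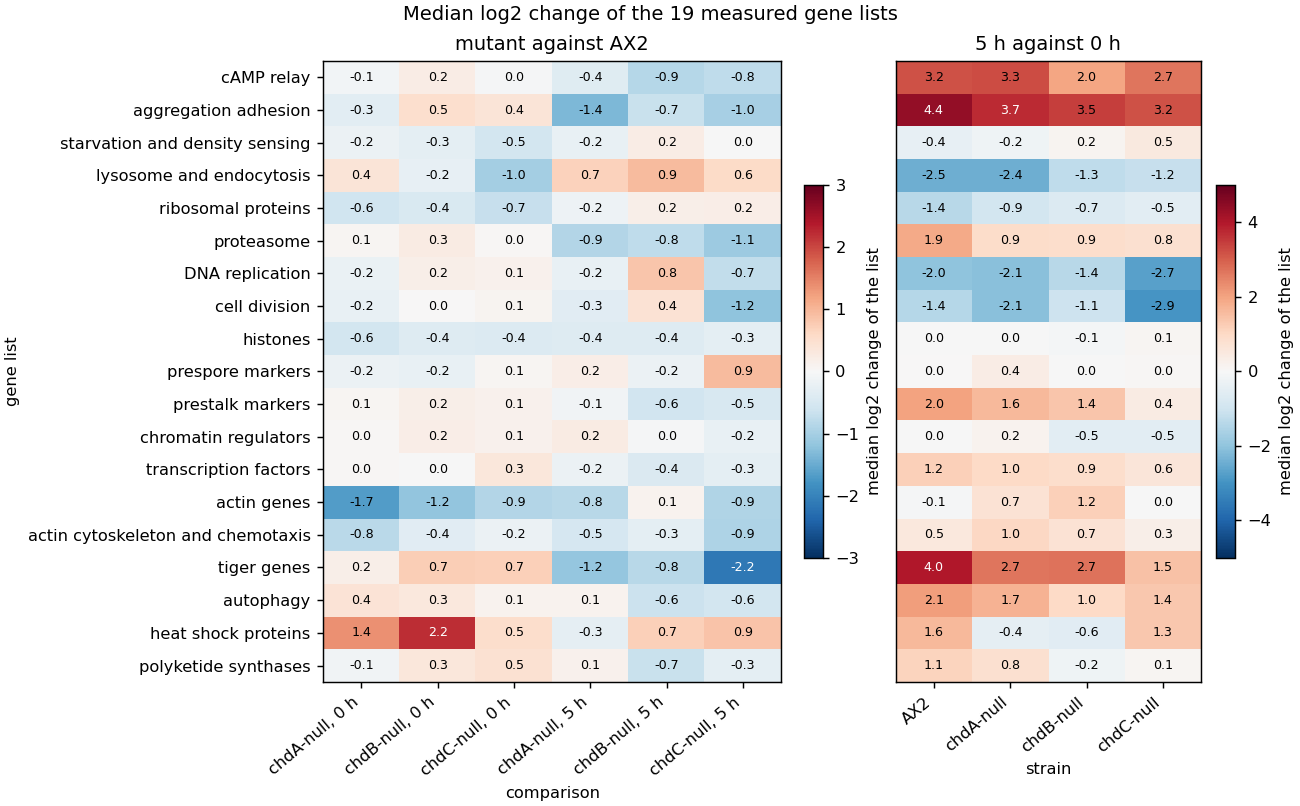
Median log2 change of each of the 19 measured gene lists (vertical) for each mutant against AX2 and, on the right, for 5 h against 0 h in each strain, printed and coloured. Actin genes were lowest in growing chdA-null, and tiger genes in chdC-null at 5 h, while at equal totals, which raise all genes alike, among lists past camera the median turned positive for the actin cytoskeleton in growing chdB-null and chdC-null, for starvation, lysosome, prespore and transcription factor genes in growing chdB-null, and for cAMP relay and cell division genes in chdA-null at 5 h.

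The mutants were compared with each other by the genes they shared against AX2. At 0 h, 401 genes were higher and 139 lower in all 3 mutants, and at 5 h 685 and 897. Among growing cells, chdA-null and chdB-null shared 616 higher genes where independence gives 181, and 236 lower genes where it gives 38.9, chdA-null and chdC-null 642 (242) and 388 (127), and chdB-null and chdC-null 692 (231) and 167 (37.5). At 5 h the shared genes were 825 higher (292) and 1044 lower (540.4) for chdA-null and chdB-null, 1357 (522) and 1244 (510.1) for chdA-null and chdC-null, and 1042 (413) and 2038 (1126) for chdB-null and chdC-null. Across all 9982 genes, which are not independent replicates, the log2 differences of these 3 pairs correlated with r = 0.55, 0.40 and 0.44 at 0 h and 0.50, 0.63 and 0.51 at 5 h, where simulated groups sharing only the AX2 libraries gave 0.50. Covariances were 0.322, 0.309 and 0.278 at 0 h and 0.336, 0.616 and 0.538 at 5 h, against 0.0346 simulated, and the sign was the same in 65.9%, 59.3% and 64.9% of genes at 0 h and 68.7%, 75.7% and 73.1% at 5 h, against 66.7% simulated. The 2 AX2 libraries per stage are too few to divide, so the excess was not separated from what shared AX2 values give.

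Whether loss of a remodeler altered the change from growth to 5 h of cAMP pulses was tested as the difference between a mutant's 5 h change and that of AX2. limma called 1510 genes with a higher and 1485 with a lower change in chdA-null (50.4% higher, 40.1% at equal totals), 888 and 3265 in chdB-null (21.4%, and 52.3% under TMM scaling), and 1769 and 2864 in chdC-null (38.2%, and 52.0% under TMM scaling). At 2-fold, without a test, these were 1435 and 1337, 766 and 2520, and 1569 and 2248, against 1104 and 1561 for chdA-null at equal totals and 1489 and 1399 for chdB-null and 2073 and 1658 for chdC-null under TMM scaling. Proteasome genes rose less than in AX2 in every mutant, 28, 30 and 33 of 40 in chdA-null, chdB-null and chdC-null, with medians of -0.96, -0.49 and -0.91 relative to all genes (camera adjusted p = 1.3e-08, 0.00011 and 2.3e-06, and adjusted p = 0.31, 0.54 and 0.42 with an estimated correlation). Tiger genes did so too, 12, 19 and 19 of 22, with medians of -1.49, -1.18 and -2.83 (camera adjusted p = 0.00052, 0.0037 and 5.9e-06, and adjusted p = 0.18, 0.28 and 0.084 with an estimated correlation). Adjusted over the list alone, 29, 32 and 36 proteasome genes and 13, 19 and 19 tiger genes passed in this direction. Under TMM scaling the proteasome genes with a lower change were 29, 11 and 25, and the tiger genes 13, 11 and 19. Strain effects common to both stages were tested in the additive model, with 3 residual degrees of freedom. The residual also holds strain differences in the 5 h response, so few calls do not show that few common effects exist. For chdC-null limma called 90 genes higher and 34 lower, and for chdB-null 0 higher and 1 lower, with 432 at an unadjusted p under 0.05. That gene was gefJ (log2 -4.81 ± 0.46, adjusted p = 0.012), named after its values were seen in this model. It was 37.9 at 0 h and 8.06 at 5 h in chdB-null, against 781 and 553 in AX2, 775 and 573 in chdA-null and 959.7 and 394 in chdC-null. With the other mutants left out, the counts were 317 in chdC-null and 101 in chdB-null, and with no filter on low values the call of gefJ ended, with 0 genes in chdB-null. For chdA-null limma called 0 genes, with 558 at an unadjusted p under 0.05 and a smallest adjusted p of 0.11. No list called by camera in the additive model kept its call with an estimated correlation, where the smallest adjusted p was 0.90. fry, which asks whether the genes of a list move 1 way without comparing them with other genes, passed in the additive model for histones in chdA-null, chdB-null and chdC-null (median log2 -0.48, -0.37 and -0.39, adjusted p = 0.037, 0.040 and 0.037). AX2 had the largest totals, so equal totals would raise these medians. Whether the histone calls hold at that scaling was not tested. For the stage effect fry passed for cAMP relay, aggregation adhesion, DNA replication, prestalk, transcription factor, tiger and autophagy genes (adjusted p of at most 0.040). Of the 104 camera calls on the split libraries, 95 had a median outside the middle 95% of random lists matched on expression.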

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

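The tests of a difference between stages on the split libraries, the equal-totals test of the library factors and the comparison of length trends between the chdC-null libraries were chosen after the results were seen. The change from 0 h to 5 h differed from that of AX2, by a test of the difference itself (limma), in 2995 genes in chdA-null, 4153 in chdB-null and 4633 in chdC-null. List medians of that difference passed camera in all 3 mutants for ribosomal proteins (0.43, 0.58 and 0.89 in chdA-null, chdB-null and chdC-null), the proteasome (-0.93, -0.94 and -1.12) and tiger genes (-1.45, -1.64 and -3.04). In chdB-null and chdC-null they also passed for starvation and density sensing (0.47 and 1.13), lysosome and endocytosis (1.18 and 1.63) and cell division (0.31 and -1.32), and in chdA-null and chdB-null for actin genes (0.83 and 1.33). In chdB-null cAMP relay (-1.01), DNA replication (0.61), the actin cytoskeleton (0.13) and polyketide synthases (-1.18) passed as well, and in chdA-null heat shock proteins (-1.45). The mutants were not tested against each other, and cAMP relay moved as far in chdC-null without passing (-0.56 relative to all genes in both). The values above are not relative to all genes, whose median of the difference was -0.45 in chdB-null. Relative to it, the chdB-null medians were 1.03 (ribosomal), -0.49 (proteasome), -1.18 (tiger), 0.93 (starvation), 1.63 (lysosome), 0.77 (cell division), 1.79 (actin), 1.07 (DNA replication), 0.58 (cytoskeleton) and -0.73 (polyketide synthases). In chdB-null the cell division call ended under TMM scaling (camera adjusted p = 0.055) and in the shortened lists, and the actin cytoskeleton call at equal totals (camera adjusted p = 0.050). None of these list calls held with a correlation estimated over all members, where the smallest adjusted p was 0.084 (tiger genes, chdC-null). Over members divided in all groups, chosen after seeing the data, cAMP relay in chdB-null (0.030), lysosome genes in chdB-null and chdC-null (0.029 and 0.040) and starvation and tiger genes in chdC-null (0.044 and 0.012) passed. Of the 16 genes named per mutant at 0 h, 15 in chdA-null, 15 in chdB-null and 9 in chdC-null differed from AX2 to another extent at 5 h, and of the 16 named at 5 h, 16, 15 and 10 at 0 h. These genes were chosen for the largest differences at 1 stage, which favours such counts.

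More genes were lower than higher in chdB-null at 5 h, 65.9% of the 2-fold genes as deposited. Removing a trend with gene length left 66.3%, but the trend was only -0.09 log2 and the median of all genes was kept, so this decides nothing on gene length bias. The library factors stay open too: lower genes were 39.8% at equal totals and 41.9% under TMM scaling, but equal totals also moved chdA-null at 5 h from 45.7% to 15.8%, so the factors and a lower level of many transcripts cannot be told apart.

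Longer genes were higher in growing chdC-null than in AX2, by 0.42 log2 between the longest and shortest of 5 bins of length. The trends of the 2 libraries against AX2, 0.67 and 0.20, differed by 0.46 as bin medians, which is consistent with a length bias of single libraries. With the trend removed, 86.9% of the 2-fold calls stayed 2-fold. The medians of the bins, -0.14 to 0.28 log2, are small beside a 2-fold change, so only calls near the threshold could be lost. The average trend alone therefore does not give most of these calls, but this could not show whether single genes carry a larger length bias. An effect of chdC loss on long genes stays untested.

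The changes from 0 h to 5 h were smaller in the mutants than in AX2. With the other mutants' change as an instrument, which removes the effect of noise in AX2, the slopes were 0.816 in chdA-null (0.798 to 0.835 over 16 choices of libraries), 0.734 in chdB-null (0.718 to 0.751) and 0.702 in chdC-null (0.642 to 0.763), so noise is not the cause. Over 2999 genes with all values at 500 or more they were 0.799, 0.729 and 0.689, so compression of low values by the number added is not the cause either. A smaller or later response of the mutants may underlie this, but all 3 share the same AX2 libraries, and AX2 cells that happened to be ahead could give it too, which was not tested. The same sharing of AX2 could add to the excess of genes shared between the mutants.

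For the stage effect common to the 4 strains, 8 splits of the samples part the 2 stages of every strain, too few for a share under 0.05. Only the real split, 1 of the 8, gave 6600.0 genes, and the highest of the others gave 0.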

How the results depend on the processing

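All alternatives on the split libraries, equal totals for genes and lists, and the removal of a length trend were chosen after seeing the data. No paired analysis was possible because the columns merge the 2 replicates without their numbers, and the split libraries cannot be matched to them. The count comparisons foreseen for separate replicate columns, the replicate block and the count-model tests were not run, since no column holds whole counts. Of 30 counts, all stayed within 1.5 times under TMM scaling and with 1 or 20 added, and of 13 counts of 2-fold genes all did with no minimum and with the length trend removed. The chdB-null count at 0 h was 609 with a minimum of 200, by construction. With 3-fold in place of 2-fold, also by construction, the counts were 592, 377 and 614 at 0 h (chdA-null, chdB-null, chdC-null), 504, 578 and 1386 at 5 h, 3442 for the stage change in chdB-null, and 1220.0, 1417 and 1709 for the differences of differences. At equal totals the 2-fold counts at 0 h were 2022, 1490.0 and 2160.0, and the limma counts on the split libraries 4944, 4662 and 5501, because AX2 had the largest totals and equal totals move every gene of a library by 1 factor. Requiring 2-fold beside the adjusted p gave 1408, 1086 and 1588 at 0 h and 1715, 2198 and 3506 at 5 h, by construction. Without chdB-null 0 h library 2, chdC-null 0 h library 1 and chdB-null 5 h library 2, the counts at 0 h were 1008 in chdB-null and 1715 in chdC-null, with fewer libraries. Leaving out 1 library at a time gave 1604 to 1949 (chdA-null), 914 to 1317 (chdB-null) and 1771 to 2580.0 (chdC-null) at 0 h, and 2153 to 3057 for chdA-null at 5 h, with the lone library assumed to vary like the other groups. The lowest of these were without chdA-null 0 h library 1 (without library 2, 1643), chdB-null 0 h library 2 (without library 1, 938, without AX2 library 2, 1038), chdC-null 0 h library 1 (without AX2 library 2, 1894) and AX2 5 h library 2. In the additive model chdB-null had 0 genes with no filter, where more genes were tested, and with the other mutants left out the counts were 0 for chdA-null, 101 for chdB-null and 317 for chdC-null; the cause was not tested. At equal totals 8 medians of lists past camera reversed, through the same shift of all genes: cAMP relay 0.046 and cell division 0.057 in chdA-null at 5 h, starvation 0.10, lysosome 0.14, prespore markers 0.14, transcription factors 0.36 and actin cytoskeleton 0.037 in chdB-null at 0 h, and actin cytoskeleton 0.30 in chdC-null at 0 h. Changes of sign in lists that passed camera in neither scaling were not counted. Of 423 results, the 16 largest changes per comparison and the list medians, 417 kept their side of the threshold under TMM scaling, and their direction where past it. At equal totals 389 of the 407 tested did. Direction was not compared for results that did not pass. Of 631 called list members beyond these, 612 kept their call under TMM scaling and 592 at equal totals, and other values added were not run for them. The disrupted genes kept their calls in their own mutants, but the lower chdC at 5 h in the other 2 lost its call at equal totals (adjusted p = 0.39 in chdA-null, 0.15 in chdB-null). With an estimated correlation 103 list calls were lost, and 71 with that of the divided members. Of 221 list shifts, shortened lists without low members ended 2 calls (cell division in the chdB-null difference, heat shock proteins in chdC-null at 5 h) and added 6, while the actin and tiger lists, which hold similar copies, were left out whole, so sharing of reads among copies was not tested. A 2-fold change was found for 62% of simulated genes, so changes of that size are often missed. Smaller changes and other depths were not simulated.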

Other observations

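The removal of a length trend and the comparisons of the split libraries below were chosen after seeing the data. Of 11 small nuclear RNA genes, 6 were called higher and 2 lower in chdC-null at both stages, with a median log2 of 1.31 at 0 h and 1.47 at 5 h, against 1754 and 1107 (0 h) and 2715 and 3258 (5 h) of all 9982 genes. The 2 growing chdC-null libraries differed by a median of 0.93 log2 over these 11 genes, and the group was not tested. Of 70 pseudogenes, 48 were called higher and 12 lower in AX2 at 5 h (median log2 1.80), against 4486 and 3637 of all genes, and the group was not tested. In growing chdB-null, library 2 stood above library 1 by up to 5.69 log2 among 5 small nucleolar RNA genes and up to 3.47 among 11 small nuclear RNA genes. Between the 2 libraries of chdB-null at 5 h the trend from the shortest to the longest genes differed by -0.72 log2, and between those of growing chdC-null by -0.55, here as bin medians of the gene-by-gene difference between libraries, without AX2.

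A hypothesis, whose test was set before its result was seen, was that growing mutants already express part of the 5 h programme. Across 9982 genes, which are not independent replicates, the 0 h difference of a mutant from AX2 and the mean 5 h response of the other mutants correlated with r = 0.247 in chdC-null (0.218 to 0.264 over the choices of libraries, Spearman's rho 0.290), above the 0.2 foreseen, so growing chdC-null cells may express a small part of that programme. In chdA-null r was 0.187 (0.164 to 0.194, rho 0.193) and in chdB-null 0.126 (0.113 to 0.129, rho 0.133), which left the question undecided for both. Each r was positive, and each mutant was set against the same growing AX2 libraries. Growing AX2 cells that happened to be behind could give such correlations too, also in chdC-null, which was not tested. Between the shortest and longest of 5 bins of length, growing chdC-null rose by 0.42 log2 against AX2, growing chdA-null by -0.09 and growing chdB-null by 0.009. The 5 h response rose with length too, by 1.04 log2 in chdA-null and 0.69 in chdB-null. No r was computed with these trends removed, so in chdC-null a shared length trend was not separated from a shared programme.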
